A study of Caenorhabditis elegans with 2 samples.

How the data were processed

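ChIP-seq was done on 2 biological replicates of L1 larvae expressing SWSN-7 tagged with GFP and FLAG, and both replicates formed the only group. Per the labels, the precipitation used an antibody against GFP and chromatin was fragmented by sonication. Another label field names swsn-7 as the antibody, which was read as the target. A control experiment is named in the labels, and the authors called candidates relative to a control. Its data were not used here, so no background measured in control chromatin could be set beside the values. The labels call the replicates biological, and nothing else about separate cultures is stated.

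Per the readme deposited with the samples, the authors mapped the reads to builds ce10 and ce11 and made a list of candidate peaks and background for each replicate and for the pooled replicates. They then made a list of regions passing the IDR threshold from these. The aligner, the peak caller, their versions and the filters are not given in the sources used here. The authors' lists give each region's position, the caller's signal value (a measure of enrichment that is comparable within a list only), a −log10 q-value and the summit. The deposited −log10 q-values shared a ceiling over all 4087 IDR entries in ce11, so they could not rank the strongest regions, and the signal value was used for every ranking. Signal value is the authors' and was used only to describe, rank and filter regions. Each candidate list held exactly 30000 entries, so its lower end is set by that number and not by a threshold. No entry had the same region and signal in both replicates, so neither list was a copy of the other. That check cannot tell biological from technical replicates, and the replicates were counted as separate because the labels call them biological. Read depth is unknown, and no interval that needs it is given. Copies of a repeated gene can share reads, and how the authors treated such reads is not given in the sources used here.

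Entries overlapping by at least 1 bp were merged, keeping the summit and signal value of the strongest. Coordinates are 1-based. All positions, genes and sequences refer to ce11, which is the WBcel235 assembly, with gene models of Ensembl release 115. The ce10 lists were used only for counts, chromosomes and signal values, and no coordinate was converted. A promoter was the window from 1000 bp upstream to 500 bp downstream of the 5′ end of a protein-coding transcript, and a gene was called bound when an IDR summit lay in it. In C. elegans many transcripts are trans-spliced, so annotated 5′ ends can lie downstream of the true start of transcription. This can move a summit's apparent distance upstream.

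Promoter shares, replicate overlap and tRNA overlap were tested by 1000 random placements within each chromosome, one-sided. Sets of regions, genes and windows were compared by Fisher's exact test, two-sided, with conditional odds ratios and exact intervals. Benjamini-Hochberg adjustment ran over 41 gene lists and, separately, over 14 motifs. Protein-coding lists were set against all other protein-coding genes, and noncoding lists against all other genes. GC content was tested with 100000 sign flips. Motifs were searched on both strands in 200 bp windows, with flanks 500 bp away matched in 5 percentage point bins of GC content. These tests treat regions or genes as the units and describe these libraries. The spread between libraries rests on 2 replicates. Neighbouring genes can share a region. For protein-coding lists this was addressed by 10000 rotations of bound labels along the gene order. For all lists it was addressed by keeping only the nearest 5′ end.

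Lists, motifs, tests and the alternatives not listed below as added later were chosen before the data were examined. The genes named in the text were taken by a rule of that kind. It takes genes at the 25 IDR regions with the highest signal value, up to 4 bound members of each list that passed, by signal value, up to 2 of every other list, and swsn-7, unc-119 and the SWI/SNF subunits. Members of the noncoding lists and the pair of genes at 1 region on chromosome IV are not named, and the neighbours of named genes and the 2 regions in unc-119 were added after their values were seen. Some lists share members: swsn-4 is in both the SWI/SNF and the chromatin list, lin-35 in both the cell cycle and the chromatin list, and all 6 Hox genes are in the homeobox list. Alternatives were the strongest 1988 regions, each replicate's strongest 4087 entries alone, promoter windows of 300 bp on each side and of 2000 bp upstream, other overlap rules, other windows and backgrounds for sequence, and the ce10 lists. Those added later are named in the closing section. Of the results planned before the data were examined, 1 description of the replicates and its 2 alternatives are left out of the text.

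The tests of gene lists, promoter share, overlap, motifs and GC content were tested on simulated data, and those of the X and arm shares were not. Of 100 lists given a raised rate over 19973 genes 99 were recovered, and 4 of 480 unchanged lists were called, by Fisher's exact test and with the same counts by rotation. Bound labels were drawn independently for each gene, so these counts do not cover neighbouring genes that share a region. The raised lists were repeated draws of a few larger ones, so recovery of lists as small as the 13 SWI/SNF subunits was not tested. The model with GC content called 50 of 50 lists with an effect and 3 of 50 without. The promoter test called 50 of 50 raised sets of 4000 regions and 2 of 50 random ones. The overlap count found 318 of 318 overlaps and 0 among 1182 regions without one. The motif test with 5 point bins found the planted motif and also called 1 of 13 unplanted motifs, where simulated summit windows were richer in GC. With 1 point bins it called 0 of 13, and these bins were added as an alternative. The software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6.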

Results

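Binding of SWSN-7, an ARID-domain subunit of the PBAF class of SWI/SNF chromatin remodelling complexes, was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in whole Caenorhabditis elegans hermaphrodites at the L1 larval stage. The animals were of strain OP512, which carries a transgene for SWSN-7 with a GFP-FLAG tag at its C terminus and a mutation of unc-119. They were collected 6 hours after synchronization by starvation of hatched L1 larvae, and chromatin was precipitated with an antibody against GFP. The series held 1 group of 2 biological replicates, so no groups were compared. The question addressed was where in the genome the tagged protein was found. The files gave regions with the peak caller's signal value and no read counts, so the sequencing depth of each replicate is unknown. Confidence intervals of shares are exact (Clopper-Pearson, 95%) and cover counting error over regions or genes. The 2 replicates' own values are given beside the main shares as a measure of the spread between libraries.

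The authors' list of regions passing the irreproducible discovery rate (IDR) threshold held 4087 entries in genome build ce11, which merged into 3976 non-overlapping regions, hereafter IDR regions. They covered 1.26% of the 6 chromosomes, and the median entry was 362 bp wide. The pooled candidate list, capped at 30000 entries, merged into 26121 regions, of which 22146 overlapped no IDR region and served as weaker candidates from the same libraries. That list holds peaks and background, and its −log10 q-values fell to 0.162. The weaker candidates may therefore hold much background, and comparisons with them are not comparisons with weaker binding sites alone. When the strongest 4087 entries of each replicate's own list were compared, 3341 of 3949 merged regions of replicate 1 (84.6%, interval 83.4 to 85.7) overlapped a region of replicate 2 by at least 1 bp. Random placement of replicate 2's regions within their chromosomes gave a mean of 2.63% and a maximum of 3.55% over 1000 placements (permutation test, one-sided, p = 0.001, the smallest it can give). Both strongest sets overlapped 83.6% of the IDR regions, and 0.453% were overlapped by neither. The lists' signal values are not on a common scale. Across the 3966 IDR regions with a match in both replicate lists, replicate 2's values were higher by a median of 0.44 on the log2 scale (SD 0.46).

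**Figure D1:**
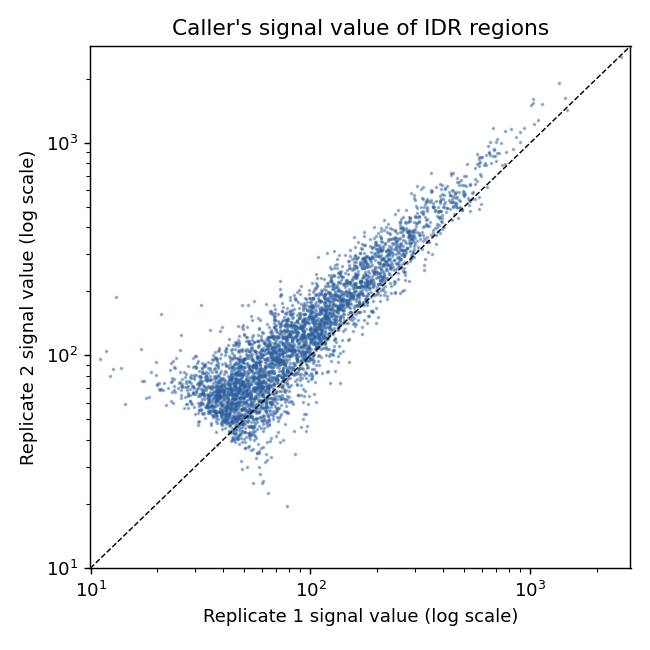
Caller's signal value in replicate 1 (x axis, log scale) and replicate 2 (y axis, log scale) for the 3966 IDR regions matched in both lists, 1 point per region, with the line of equal values dashed. The points follow a single band that lies above the line for most regions (median log2 difference 0.44), and the scatter widens toward low values.

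The region with the highest signal value (5142.4 in the pooled list, rank 1 in both replicates) had its summit at -569 bp from the 5′ end of egg-5, a gene of the egg-to-embryo transition, on chromosome I from 4171893 to 4172635. Among the strongest 10 regions, 4 lay at ribosomal protein genes, namely rpl-3 (3233.9, chromosome III, 3867348 to 3867826, at -283 bp), rpl-20, rpl-15 and rpl-35. The region at rpl-20 (2635.3) lay closer to the 5′ end of Y17G9B.5, at -175 bp, than to that of rpl-20, at -287 bp. The region in the promoter window of H41C03.3 (3023) had its summit at -960 bp. The nearest 5′ end there was that of ZK1248.17, with the summit at 724 bp and so outside its window. Others among the strongest 25 lay at cdc-48.1 (2608.4), which encodes an AAA ATPase of protein quality control, tasp-1 (2545.8), the promoters of a pair of genes on chromosome IV (15646303 to 15646994, 2339.7) and cox-5A (2005.2), a subunit of cytochrome c oxidase. Further ones lay at tag-340 and its neighbour nhl-2 (1921.8), the histone gene his-37 (1861.6), puf-9 (1842.7), an RNA-binding protein gene, and tos-1 (1755.9). The region at rps-1 (1735.7) also lay in the promoter window of ifet-1, that at his-68 (1734.2) in the windows of his-67 and alg-5, and that at Y22D7AL.10 (1672.9) in that of hsp-60. The 25th, at 1613.5, lay inside pbrm-1, which encodes another PBAF subunit, at -781 bp from an internal transcript start. Of the strongest 25, 7 had no protein-coding promoter. The summit of 1 lay in the noncoding gene linc-128 (chromosome V, 1151283 to 1151771) and that of another in an intron of Y111B2A.12 (chromosome III, 12612413 to 12612930). The remaining 5 were intergenic, on chromosome II from 5543327 to 5544497, on V from 20778133 to 20778724, on III from 4281896 to 4282655, and on X from 11093840 to 11094489 and from 4208945 to 4209616.

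IDR regions were concentrated at promoters. Of the 3976 summits, 2498 (62.8%, interval 61.3 to 64.3) lay between 1000 bp upstream and 500 bp downstream of an annotated 5′ end of a protein-coding transcript. The strongest regions of replicate 1 gave 61.8% and those of replicate 2 gave 62.6%. Random placement gave 31.3% ± 0.698 (SD over 1000 placements, maximum 33.7%, permutation test, one-sided, p = 0.001, the smallest it can give). Of the weaker candidates, 36.1% lay in such a window (odds ratio 2.99, interval 2.79 to 3.21, Fisher's exact test, two-sided, p = 6.89e-216). The summits sat mostly just upstream: of the 2615 within 1000 bp of the nearest 5′ end, whose median position was -173 bp, 87.2% were upstream, against 55.2% of the 9777 such weaker candidates. As shares of all regions of each set, IDR summits outside promoter windows fell in introns (12.4%, against 22.2% of weaker candidates) and between genes (20.5% against 25.3%). The higher promoter share of IDR regions leaves less for every other class, so these shares show no avoidance of introns or intergenic sequence. Among the 1478 IDR summits outside promoter windows, 815 lay between genes and 494 in introns, against 5601 and 4921 weaker candidates. Noncoding genes held a larger share of IDR summits (3.14% against 2.24%, odds ratio 1.42, interval 1.15 to 1.73, exact test, adjusted p = 0.000975). IDR summits were scarce in coding exons (0.352% against 10.6%, odds ratio 0.0297, interval 0.0162 to 0.05) and 3′ UTRs (0.578% against 3.24%, odds ratio 0.174, interval 0.109 to 0.263). In all, 3176 of 19973 protein-coding genes (15.9%) had an IDR summit in the promoter window and are called bound here. Of the 2498 regions, 794 lay in the windows of more than 1 gene.

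**Figure D2:**
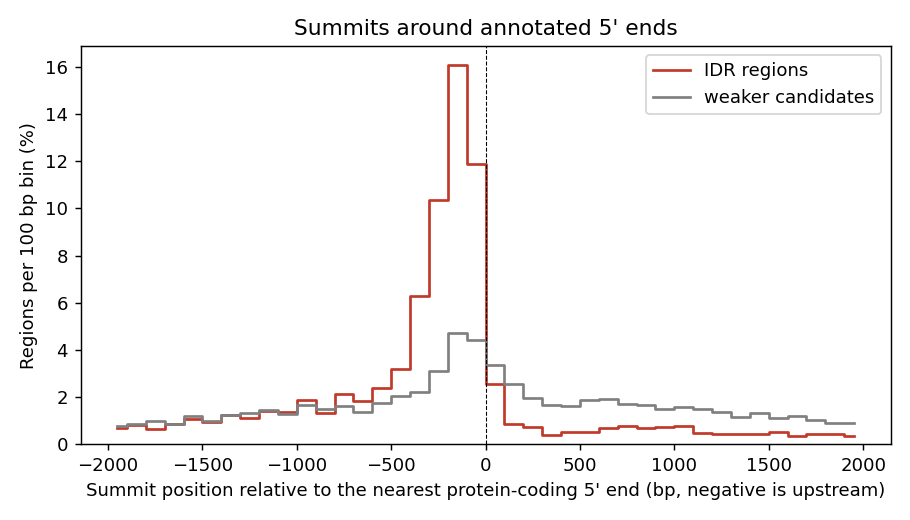
Share of regions per 100 bp bin (y axis, percent of all regions of that set) by the position of the summit relative to the nearest 5′ end of a protein-coding transcript (x axis, bp, upstream negative). IDR regions (red) peak just upstream of the 5′ end, while weaker candidates (grey) show a low peak, with 87.2% and 55.2% of the summits within 1000 bp lying upstream.

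Genes of protein synthesis and turnover were bound far more often than other genes. Of 80 cytosolic ribosomal protein genes, 68 were bound (85%, interval 75.3 to 92; 83.8% and 85% with replicates 1 and 2 alone), against 15.6% of other genes (odds ratio 30.6, Fisher's exact test, adjusted p = 1.5e-41). The odds ratio was 7.5 with the nearest 5′ end alone and 7.82 in a window of 300 bp on each side, the narrow window. Of 38 translation factors, 27 were bound (71.1%, odds ratio 13.1, exact test, adjusted p = 2.87e-13), led by iff-2 (1517.7), eif-3.C (1044.8), eef-1A.1 (935.3) and eif-3.B (887.4), and the lowest odds ratio was 7 among the strongest 1988 regions. Of 33 proteasome subunits, 24 were bound (72.7%, odds ratio 14.2, exact test, adjusted p = 2.86e-12), led by rpn-3 (1125.9), rpt-2 (487.9), rpn-11 (450.7) and pbs-1 (435.9), and the lowest odds ratio was 5.49 among the strongest 1988 regions. Chaperones were bound in 27 of 60 cases (45%, odds ratio 4.36, exact test, adjusted p = 3.04e-07), with hsp-60, hsp-90 (1595.1), hsp-1 (1539.5) and dnj-13 (1507) highest. With the nearest 5′ end alone this call was lost (odds ratio 1.85, exact test, adjusted p = 0.109, the highest over 9 alternatives that began at 1.49e-09). Respiratory chain genes were bound in 20 of 35 cases (57.1%, odds ratio 7.09, exact test, adjusted p = 9.81e-08), led by cox-5A, cox-5B (1025.2), atp-1 (900.2) and cox-6B (861.9). Vacuolar ATPase genes were bound in 9 of 20 cases (45%, odds ratio 4.34, exact test, adjusted p = 0.00331), led by vha-12 (732.1), vha-8 (634.3), vha-15 (423.7) and vha-13 (360.8). In the narrow window the vacuolar ATPase genes did not pass (odds ratio 0.994, exact test, adjusted p = 1), while over 9 alternatives adjusted p ran up from 0.000179.

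Regulators of chromatin and of the cell cycle were also bound more often. Among 58 chromatin regulators 32 were bound (55.2%, odds ratio 6.56, exact test, adjusted p = 3e-11), led by the histone acetyltransferase gene cbp-1 (1606.3), the methyltransferase gene set-16 (1550.7), lin-54 (1447.5) of the DRM complex and bet-2 (1187.2). In the narrow window the odds ratio was 3.73. Among 48 genes of the cell cycle and DNA replication 29 were bound (60.4%, odds ratio 8.14, exact test, adjusted p = 1.42e-11), with pcn-1 (1082.3, PCNA), efl-1 (849, an E2F factor), lin-35 (653.7, the Rb homologue) and cdc-6 (647.1) highest. Among the strongest 1988 regions the odds ratio was 3.96. The heterochronic pathway, which times larval development, had 9 of 20 genes bound (45%, odds ratio 4.34, exact test, adjusted p = 0.00331), namely nhl-2, ain-1 (882.4), lin-28 (649.3), lin-66 (614.9) and 5 others. In the narrow window that call was lost (odds ratio 1.58, exact test, adjusted p = 0.554), and the lowest of 9 alternatives was 4.38e-06, with the window reaching 2000 bp upstream (odds ratio 9.36). Insulin and dauer pathway genes were bound in 10 of 33 cases (30.3%, odds ratio 2.3, exact test, adjusted p = 0.0445), led by ftt-2 (938.1), rict-1 (443.8), akt-2 (322.7) and daf-3 (303). The call ended under 4 of 9 alternatives, which ran from 0.000382 to 1, among them the permutation test that rotates bound labels along the gene order (adjusted p = 0.0926). In the narrow window the odds ratio was 0.895 (exact test, adjusted p = 1), and with the window reaching 2000 bp upstream it was 3.78.

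Tissue lists differed from one another. Chromatin came from whole animals, so a gene not called bound here may still be occupied in a small share of the cells. Pan-neuronal genes were bound in 19 of 45 cases (42.2%, odds ratio 3.88, exact test, adjusted p = 6.36e-05), led by egl-30 (1609.5, a Gq protein), unc-16 (742), unc-76 (546.3) and unc-14 (461.8). The odds ratio was 2.56 in the narrow window and 9.92 with the window reaching 2000 bp upstream. Body wall muscle genes were bound in 19 of 51 cases (37.3%, odds ratio 3.15, exact test, adjusted p = 0.000362), led by act-4 (341.3), act-2 (316), unc-112 (312.4) and unc-60 (222). Among the strongest 1988 regions the muscle list did not pass (odds ratio 1.04, exact test, adjusted p = 0.877), nor did it in the narrow window (0.151), while the lowest of 9 alternatives was 8.41e-06. By contrast, 0 of 33 pharyngeal genes (upper bound 10.6%, adjusted p = 0.0106) and 2 of 48 intestinal genes (4.17%, nhr-49 at 504.1 and erm-1 at 244, adjusted p = 0.0396) were bound by the same exact test. The pharynx call was lost among the strongest 1988 regions (exact test, adjusted p = 0.102) and in the narrow window (0.124), in a range over 9 alternatives from 0.0104. The intestine call was lost under 5 of 9 alternatives, which ran from an adjusted p of 0.038 to 0.397 (exact tests and 1 permutation test). Cuticle collagens were bound in 11 of 176 cases (6.25%, odds ratio 0.35, exact test, adjusted p = 0.000355), with col-38 (546.7), col-71 (384.2), col-63 (356.8) and col-85 (300.8) highest, and an odds ratio of 0.102 in the narrow window. Neuropeptide genes were bound in 3 of 102 cases (2.94%, odds ratio 0.159, exact test, adjusted p = 0.000128), namely nlp-4 (303), flp-23 (176.4) and nlp-14 (90), and the odds ratio ran from 0.0881 in the narrow window to 0.249 with the window reaching 2000 bp upstream. Without replicate 1 it was 0.106. Insulin-like peptides were bound in 1 of 39 cases, ins-39 (735.8; adjusted p = 0.0232, exact test), a call lost under 4 of 9 alternatives that ran from 0.00594 to 0.232, among them the one without replicate 2 (odds ratio 0.293 against 0.139, adjusted p = 0.105, exact test).

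Of 1315 chemoreceptor genes 15 were bound (1.14%, odds ratio 0.0566, exact test, adjusted p = 1.38e-77), with srh-16 (640.1), sri-5 (637.5), srh-2 (537.7) and sre-23 (251.2) highest. F-box genes (21 of 322, odds ratio 0.365), C-type lectins (6 of 240, odds ratio 0.134), detoxification genes (12 of 200, odds ratio 0.335) and major sperm proteins (0 of 47, upper bound 7.55%) were each bound less often, with adjusted p of 1.32e-06, 5.82e-11, 8.63e-05 and 0.000861 by the exact test. Among the strongest 1988 regions the odds ratio was 0.179 for F-box genes and 0.0475 for detoxification genes, and in the narrow window it was 0.0743 for lectins. The highest F-box genes were fbxb-85 (946.5), fbxa-90 (849), fbxb-58 (644.7) and fbxa-83 (449.5). The region at fbxa-90 is the one at efl-1, at -957 bp from the F-box gene and -182 bp from efl-1. The highest lectins were clec-53 (290.7), clec-126 (246.7), clec-104 (218.6) and clec-57 (215.6), and the highest detoxification genes gst-27 (456.2), sod-1 (161.8), gst-5 (158.9) and gst-43 (141.1). No difference passed the threshold for nuclear hormone receptors (37 of 274, nhr-47 at 890.7 and nhr-49), homeobox regulators (9 of 98, ceh-38 at 822.7 and ceh-39 at 228.3), helix-loop-helix regulators (6 of 40, hlh-11 at 788.3 and hif-1 at 292.3) or Hox genes (2 of 6, lin-39 at 129.4 and ceh-13 at 106.7). The same held for the Wnt pathway (5 of 28, mig-5 at 1090.4 and wrm-1 at 351.8), the Notch and EGF pathways (4 of 29, sup-17 at 167.9 and lin-45 at 127), germline genes (7 of 62, spn-4 at 389.7 and mes-2 at 367.9) and molting genes (3 of 34, rab-5 at 543.2 and pan-1 at 133). It also held for epidermal regulators (1 of 20, nhr-25 at 104.3; 0 without replicate 1) and vitellogenins (0 of 6, upper bound 45.9%). Homeobox regulators passed as less often bound with the window reaching 2000 bp upstream (odds ratio 0.504, exact test, adjusted p = 0.0433, the lowest over 9 alternatives that reached 0.622). Core histones were bound in 18 of 72 cases (25%, odds ratio 1.77, exact test, adjusted p = 0.0688), with his-37 and his-67 highest. They passed as more often bound under 4 of 9 alternatives, which ran from 0.000727 to 0.479, among them the one without replicate 2 (20 of 72, exact test, adjusted p = 0.0127). Histone genes are near-identical copies, so their regions depend on how the authors placed reads that match several copies.

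**Figure D3:**
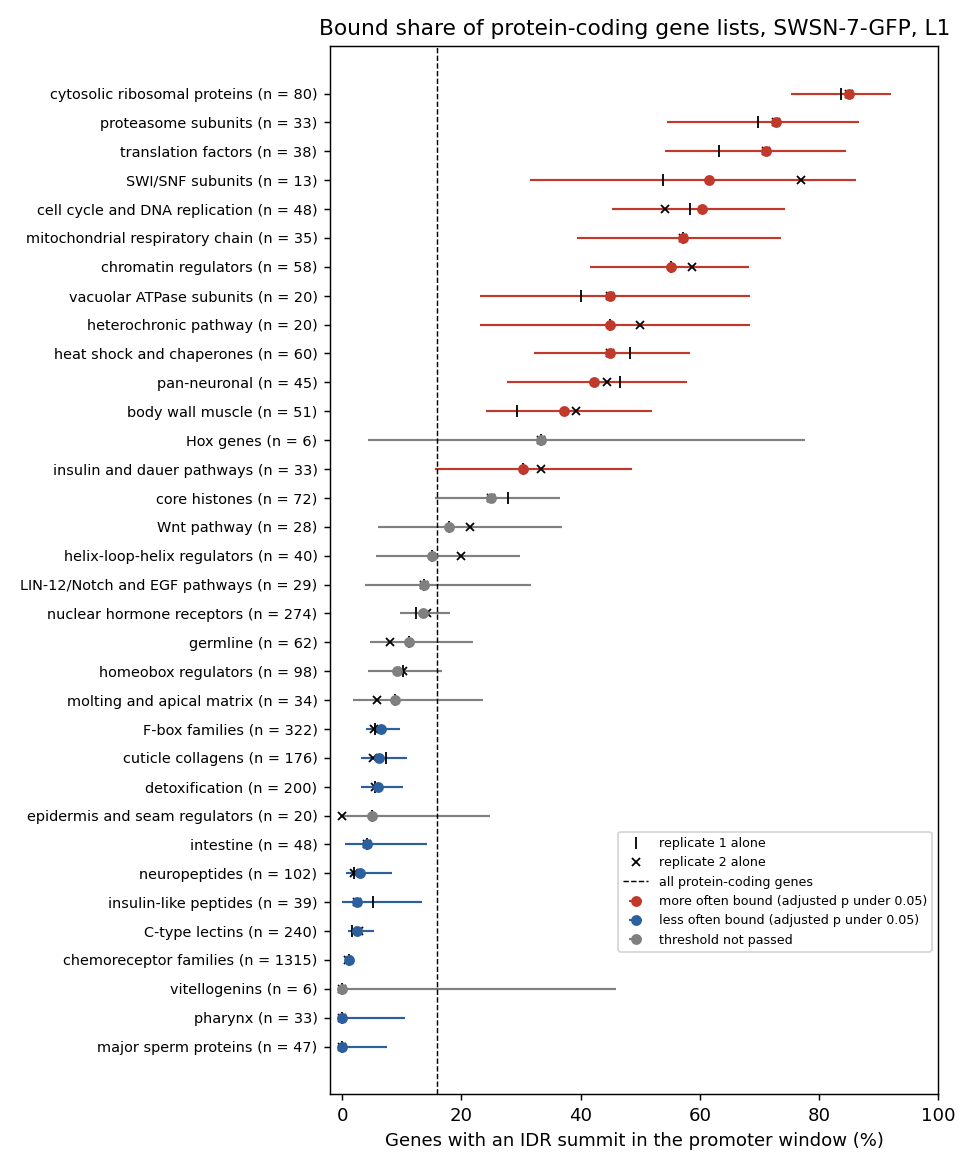
Share of each protein-coding list with an IDR summit in the promoter window (x axis, percent), with exact 95% intervals as bars and the shares from each replicate's strongest 4087 entries as ticks and crosses. Lists bound more often are red, less often blue and neither grey, and the dashed line marks the 15.9% of all protein-coding genes, with ribosomal proteins highest at 85%.

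Transfer RNA genes were a further class that IDR regions overlapped. Of 612 annotated tRNA genes, 227 (37.1%, interval 33.3 to 41.1) were overlapped by an IDR region, with 39.4% and 34.3% for replicates 1 and 2 alone. Random placement of the IDR regions overlapped a mean of 9.64 and at most 22 tRNA genes (permutation test, one-sided, p = 0.001, the smallest it can give). IDR regions overlapped a tRNA gene in 5.38% of cases, against 0.781% of weaker candidates (odds ratio 7.22, interval 5.87 to 8.91, Fisher's exact test, p = 1.93e-75). Neither comparison can tell binding of the tagged protein from recovery of tRNA genes with any antibody, since control chromatin was not analysed here. Reads shared between copies of a tRNA gene could also add to these counts. By the promoter window, which for short genes often holds a neighbour's promoter, snoRNA genes (143 of 346, odds ratio 5.82), snRNA genes (31 of 129, odds ratio 2.56) and miRNA genes (47 of 261, odds ratio 1.78) also exceeded other genes. Their adjusted p were 5.54e-47, 6.77e-05 and 0.00124 by the exact test. For miRNA genes the call was lost under 3 of 8 alternatives, which ran from 5.83e-06 to 0.516, among them leaving piRNA genes out of the background (exact test, adjusted p = 0.251). The tRNA genes by this window (264 of 612) had an odds ratio of 6.4 (exact test, adjusted p = 1.82e-91). Pseudogenes (39 of 2128, odds ratio 0.144, exact test, adjusted p = 3.61e-61) and piRNA genes (381 of 15363, odds ratio 0.142, interval 0.127 to 0.158) were bound less often. With the nearest 5′ end alone the odds ratio of piRNA genes was 0.0421. The 15363 piRNA genes are part of the background of the other noncoding lists. With them left out, the odds ratio was 4.43 for tRNA, 4.03 for snoRNA and 1.77 for snRNA genes (exact test, adjusted p = 0.0153 for snRNA genes). For pseudogenes it was 0.0969. Rotation was not run on noncoding lists, so their p-values and intervals treat neighbouring genes as independent. None of 20 rRNA genes was bound (upper bound 16.8%, adjusted p = 0.203, exact test).

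The X chromosome held 725 IDR regions (18.2%, interval 17 to 19.5; 18.1% and 18.4% with replicates 1 and 2 alone). This was above its 13.7% share of protein-coding genes (exact binomial test, two-sided, p = 9.88e-16) and below its 22.6% share of weaker candidates (odds ratio 0.762, interval 0.698 to 0.831, Fisher's exact test, p = 3.69e-10). X makes up 17.7% of the length of the chromosomes, which lies inside the interval of its IDR share. Of the 725 regions, 95 overlapped a tRNA gene, and X held 276 of the 612 tRNA genes. By length the density was 40.9 IDR regions per Mb on X, between 27.2 on V and 51.8 on III. On X, 52.7% of IDR summits lay in promoter windows, against 65.1% on the autosomes (odds ratio 0.597, interval 0.506 to 0.705, Fisher's exact test, p = 6.54e-10). Random placement also gave less on X (26.9% against 32.3%), as did weaker candidates (30.4% against 37.7%). On the autosomes, 37.7% of IDR regions lay in the outer 25% of the length at each end, the arms, and 36.1% of weaker candidates did, a difference that did not pass the threshold (odds ratio 1.07, interval 0.99 to 1.16, Fisher's exact test, p = 0.0837). Among the strongest 1988 regions the difference from weaker candidates passed (odds ratio 1.15, exact test, p = 0.00989), and without replicate 2 the odds ratio was 0.99 (p = 0.799, the highest over 4 alternatives). The arms held 44.3% of autosomal protein-coding genes, a share the IDR regions were not tested against.

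Sequence under the summits was richer in G and C than its surroundings. The 200 bp centred on the summit held 43.9% GC ± 7.14 (SD over 3976 regions), and the windows 500 bp to each side held 35.7% ± 5.54. The mean difference was 8.16 percentage points, with the summit higher in 3138 regions (78.9%; sign-flip permutation test, two-sided, p = 1e-05, the smallest it can give). Away from promoters the difference was 11.8 points, and at promoters 6.02. Of 14 motifs, 7 were more frequent in 3011 summit windows than in as many flank windows matched in GC content. The rest of the 3976 summit windows had no flank window left to match and were left out of this comparison. GA repeats occurred in 21.2% against 4.35% (odds ratio 5.91, interval 4.85 to 7.24, Fisher's exact test, adjusted p = 2.79e-90), and the odds ratio was 3.69 against shuffled windows. The B box, the internal promoter of tRNA genes, occurred in 3.32% against 0.365% (odds ratio 9.37, interval 5 to 19.4, exact test, adjusted p = 9.81e-19). For the B box the odds ratio was 2.64 in 100 bp windows (exact test, adjusted p = 0.0416, the highest over 6 alternatives) and 30.5 against dinucleotide-shuffled windows. Forkhead sites (odds ratio 2.6, and 4.88 in 100 bp windows), E2F sites (2.2), Sp1/KLF sites (1.76) and E-boxes (1.35) were also more frequent. The TATA box call (odds ratio 1.18, exact test, adjusted p = 0.0446) was lost under 3 of 6 alternatives, which ran from 2.91e-07 to 0.211, the highest without replicate 1. The E-box call was lost among the strongest 1988 regions (exact test, adjusted p = 0.433, the highest of 6 that began at 1.32e-10). The splice acceptor TTTCAG (18.9% against 33.5%, odds ratio 0.463), GATA sites (odds ratio 0.679) and heat shock elements (odds ratio 0.759) were less frequent. None of these 3 differed from dinucleotide-shuffled summit windows (adjusted p of 0.227, 0.26 and 0.221, exact test). AP-1 and homeodomain sites passed in neither direction under any of 6 alternatives. T tracts (odds ratio 1.11) passed as more frequent under 2 of 6, which ran from 0.0169 to 0.355. The nuclear receptor site AGGTCA (odds ratio 0.814) passed as less frequent under 3 of 6, which ran from 0.00905 (without replicate 1, odds ratio 0.738, exact test) to 0.222.

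**Figure D4:**
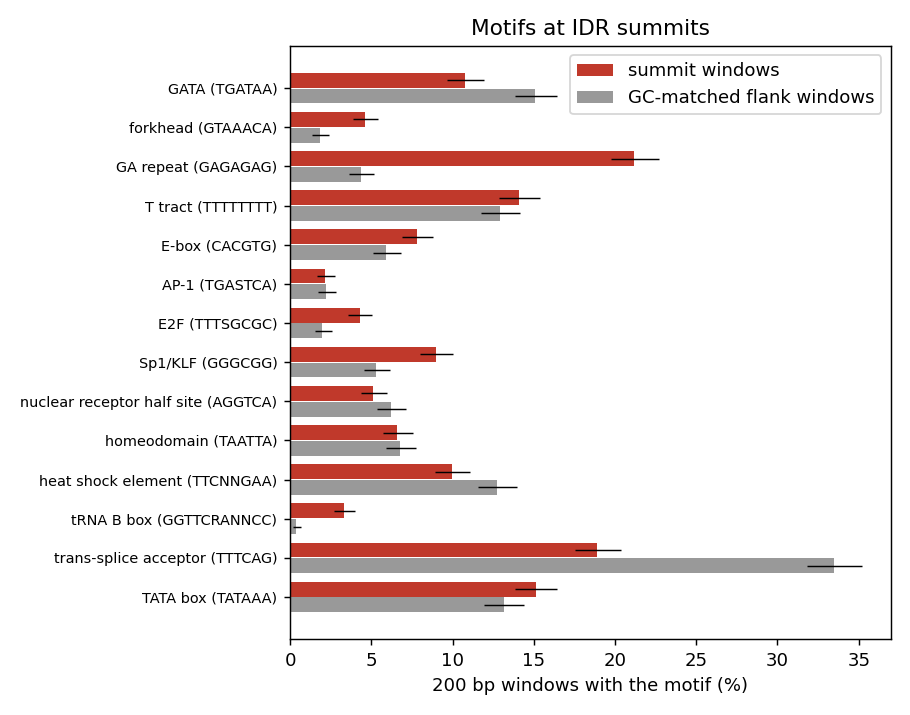
Share of 200 bp windows with each of 14 motifs (x axis, percent, either strand) in 3011 summit windows (red) and 3011 GC-matched flank windows (grey), with exact 95% intervals as bars. GA repeats (21.2% against 4.35%) and the tRNA B box (3.32% against 0.365%) stand out at summits, and TTTCAG (18.9% against 33.5%) in the flanks.

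Genes of the SWI/SNF complexes themselves were among the bound genes. Of 13 annotated subunits 8 were bound (61.5%, interval 31.6 to 86.1; 7 with replicate 1 alone and 10 with replicate 2 alone; odds ratio 8.48, Fisher's exact test, adjusted p = 0.000478). Without swsn-7, the tagged gene, 7 of 12 were bound (odds ratio 7.42, exact test, adjusted p = 0.00171), and without replicate 1 the odds ratio was 17.8. In the narrow window the call was lost (odds ratio 3.98, exact test, adjusted p = 0.0619, the highest over 10 alternatives that began at 4.82e-06). The bound genes were pbrm-1 (1613.5), swsn-7 (544.3), swsn-6 (542.7), swsn-3 (449.7), swsn-1 (243.3), the ATPase gene swsn-4 (221.3), phf-10 (152.8) and swsn-9 (100.6). Not bound were let-526, whose strongest promoter candidate had a value of 88.2, just under the lowest IDR value of 88.4, dpff-1 (80.9), snfc-5 (49) and ham-3 (38.6). The promoter window of swsn-2.2 held no candidate summit. The region at swsn-7, the tagged gene (chromosome II, 8022632 to 8027763, minus strand), had its summit at -763 bp, lay from 8028252 to 8028699 and ranked 421 of 3976. The 40 kb centred on swsn-7 held 30 pooled entries, 34 of replicate 1 and 31 of replicate 2, against a genome mean of 12 ± 7.66 (SD over 2497 windows) in the pooled list. The promoter of unc-119, the mutated marker gene of the strain (chromosome III, 10902641 to 10908935), was not bound. Its introns held 2 IDR regions, from 10903321 to 10903534 (163.7) and from 10905116 to 10905515 (140). The 40 kb centred on unc-119 held 7 pooled entries, 7 of replicate 1 and 5 of replicate 2.

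The IDR list in the older build ce10 held 5112 entries and 4940 merged regions. In both builds every IDR entry was an entry of the pooled list, and together they were exactly its strongest entries by signal value, down to 69.8 in ce10 and 88.4 in ce11. At or above the ce11 limit, the pooled ce10 list held 4085 entries, against 4087 in ce11. The X chromosome held 18.9% of the ce10 IDR regions.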

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

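The alternatives without tRNA regions, without piRNA genes, without swsn-7 in its list, with 1 point GC bins, with each replicate's list at swsn-7 and with the ce10 list at the ce11 limit were chosen after seeing the data. Promoter shares, X shares, replicate overlap and the GC difference kept their direction and their side of the threshold under all alternatives run. The promoter share ran from 42.5% (window of 300 bp) to 76.6% (all biotypes except piRNA). Taking the strongest 1988 of 3976 regions sets that number by construction, and there the arm share rose to 39.3% and passed; the cause was not tested. Against dinucleotide-shuffled windows 0 motifs were less frequent, against 3, while 7 were more frequent, as before; the cause was not tested. With 1 point GC bins 8 motifs were more frequent and 4 less. The number of lists bound more often ran from 12 to 18, against 17, with rotation (12) covering protein-coding lists only, and the number bound less often from 9 to 13, against 12. In the window of 300 bp, 7 of 29 called lists lost their call and 2 reversed without passing, the vacuolar ATPase (odds ratio 0.994) and the insulin and dauer lists (0.895). The tRNA list reversed (0.306) without regions on tRNA genes, which that setting removes. Leaving out replicate 2 ended 1 list call and added 1, and leaving out replicate 1 changed none. The arm share and the tagged gene in ce10 were not run, since ce10 lengths and gene positions were not used here. Unknown depth and the cap of 30000 entries limit what can be said of weak regions.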

Other observations

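Of the tests in this part, that of extra copies of the swsn-7 region was chosen after the result was seen. So was the criterion for neighbouring genes sharing a region, although rotation and the nearest 5′ end alone were themselves planned. Also chosen after were the 40 kb window, the counts in adjoining windows and the counts by signal rank. The bound lists also differed in how high their signal values were. The median value of bound genes was 223 over all 3176, 439 for ribosomal proteins, 442 for chaperones, 421 for chromatin regulators and 385 for the respiratory chain. It was 185 for the proteasome, 166 for the cell cycle and 124 for body wall muscle. These are descriptions with no test. Of the 2498 promoter regions, 732 lay in windows of genes on both strands.

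The X chromosome held 343 IDR regions away from promoters, and 74 of these overlapped a tRNA gene. A hypothesis is that some of them coincide with sites that recruit the dosage compensation complex, which binds X through a motif with the core GCGCAGGG. The core was present in 16 of 343 such windows of 400 bp (4.66%) and in 4 of 1135 autosomal ones (0.352%; odds ratio 13.804, interval 4.41 to 57.1, Fisher's exact test, p = 1.01e-07) and in 6 of the 10 and 10 of the 50 strongest X regions away from promoters, but also in 8 of 382 at X promoters (2.09%), a difference that did not pass (exact test, p = 0.0621). Against GC content as the cause, the odds ratio was 16.689 (interval 2.56 to 704) over autosomal windows matched in GC. Over weaker X candidates, taken as a general background of X, it was 18.891 (interval 7.79 to 48.9). Those candidates were not matched in GC content and were separated from IDR regions by signal value. Background that is strong at sites with the core would give the same result, so that comparison cannot decide on it. Windows without this exact core were not tested for recruitment, and whether strongly occupied sites are recovered without the tagged protein may only be told with a control precipitation, not analysed here.

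Candidate entries were packed around swsn-7, and extra copies of its region in the transgene are a candidate explanation. In replicate 1, 99.6% of 40 kb windows held fewer entries, which reached the level set for that explanation, and in replicate 2 98.839% did, which did not. In the pooled list, for which no level was set, 98.1% did. The adjoining 40 kb to the left held 30 pooled entries, 26 of replicate 1 and 19 of replicate 2, and that to the right 15, 15 and 18, against 30, 34 and 31 at swsn-7. IDR entries numbered 0 to the left, 8 at swsn-7 and 3 to the right. The number of promoters is argued against as the whole cause. Of the 442 windows with at least as many promoters, at most 0.6787% held as many entries in the pooled list or either replicate's list. The median of those windows was 10 or 11 entries. The window was chosen after its packing was seen, which favours a low share, and other causes of regional density were not measured. Extra copies stay open, and no biological explanation was tested.

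Growth and housekeeping lists were bound more often, as were body wall muscle and pan-neuronal genes, and pharyngeal, intestinal, collagen and neuropeptide genes less often, though of 9 alternatives the intestine call ended under 5 and the muscle and pharynx calls under 2 each. Promoter GC content is argued against as the whole cause. With it as a covariate in a logistic model across genes, 13 of 13 protein-coding lists bound more often kept adjusted p under 0.05. So did 8 of the 8 less often bound lists that could be fitted. Median promoter GC content was 34.3% for bound genes and 33.3% for all, so the model had little GC difference to adjust for. It does not cover GC content right under the summits, which unbound genes lack. Neighbouring genes sharing a region may contribute. Of the 13 lists, 11 kept their call both under rotation and with the nearest 5′ end alone, fewer than the level set to argue against sharing. With the nearest 5′ end alone the ribosomal odds ratio fell from 30.6 (interval 16.4 to 62.2) to 7.5 (4.7 to 11.9). It rose for the body wall muscle, pan-neuronal and insulin and dauer lists and fell for the others. The chaperone call ended, with an odds ratio of 4.36 (interval 2.52 to 7.48) before and 1.85 (0.894 to 3.54) after. The insulin and dauer call also ended, but with an odds ratio of 2.3 (interval 0.978 to 5.04) before and 2.37 (0.922 to 5.43) after, from 8 bound genes in place of 10, and with 10 against 5.42 ± 2.11 (SD) under rotation. Higher recovery of open, active promoters with any antibody was not tested and stays open, since control chromatin was not analysed here, and no biological explanation was tested, as the series held 1 group.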
